A study of Homo sapiens with 4 samples.

How the data were processed

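Single-nucleus RNA-seq was analysed from human liver. Nuclei had been isolated from frozen tissue embedded in OCT, a cryosectioning medium, and made into libraries with the 10x Chromium single cell 5′ kit, version 2, per the labels' protocols. In this chemistry each transcript molecule carries a unique molecular identifier (UMI), so that PCR copies count once, and each droplet carries a barcode. The label descriptions also mention perfusion, gradient centrifugation and sorting by a reporter gene. These steps do not match frozen human tissue labelled as all cell nuclei. They were read as copied from mouse samples of the study and not used, so the shares of classes given below take the nuclei as unsorted. The series has 4 libraries, 2 of non-tumour liver with background cirrhosis and steatohepatitis and 2 of hepatocellular carcinoma (HCC). The count matrices of the 2 non-tumour libraries were analysed; the HCC libraries were not analysed here, so no comparison of tumour with non-tumour tissue was made. The labels do not tie a library to a case, so the spread behind the p-values comes only from these libraries and may be technical.

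The deposited values are raw UMI counts per gene and barcode, made by the authors with Cell Ranger 5.0.1 on the genome build GRCh38, per the submitters' processing notes. Whether intronic reads were counted, and which annotation release was used, is not given in the sources used here. Each matrix lists 36601 genes and 737280 barcodes, that is, all barcodes before any calling of nuclei. Gene symbols were those of the deposited files. Positions came from GENCODE 29 on GRCh38, in which 34616 of the 36601 gene identifiers (94.6%) had a match. The matrices held 46542405 UMIs in replicate 1 and 62522078 in replicate 2.

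A barcode was called a nucleus when its UMI count reached the larger of 500 and 0.1 times the 99th percentile of the 3000 largest barcodes, with at least 300 genes and at most 10% mitochondrial UMIs. This set the UMI minimum at 2946 in replicate 1 and 4111 in replicate 2. The mitochondrial limit removed 83 barcodes in replicate 1 and 0 in replicate 2. Doublets were scored per library with Scrublet as implemented in scanpy 1.11.5. Its automatic threshold marked 4.06% of replicate 2 (160 nuclei, removed). In replicate 1 it marked 0.0799%, below the accepted minimum of 0.5%, so the nuclei with the highest 6% of scores were removed instead (216 nuclei). The nuclei kept numbered 3540, with a median of 6651 UMIs and 2648 genes, in replicate 1, and 3785, with a median of 7422 UMIs and 3052 genes, in replicate 2.

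Each library was clustered by the Leiden method (leidenalg 0.10.2, resolution 1) on a graph of 15 neighbours in 30 principal components of 3000 variable genes. The genes of the 16 lists described below were kept out of these features. Clusters were named from 111 marker genes of 14 cell classes. The markers were fixed before the data were examined, but the scoring rule was replaced after the clusters had been seen. A class's score was the mean over its markers of log2(CPM + 10), scaled from 0 to 1 across the clusters of the library. A cluster stayed unnamed when its best score was under 0.3, when an unrelated class reached 0.6 of the best score, when fewer than 3 markers were found in 10% of its nuclei, when its leading genes belonged to another class, or when its UMI count was low with no own marker among its 10 leading genes. This left 0.706% of the nuclei of replicate 1 and 11.9% of those of replicate 2 unnamed. A class name ends in "-like" because it rests on markers alone. The 14 classes held no fibroblasts other than HSC, so such cells could be named HSC-like.

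Counts were summed per library and class for the 6 classes with at least 20 nuclei in each library, and the 12 sums were tested in one fit with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr) in R 4.3.3. The library was a block in the design, since all classes of a library come from the same tissue; 5 residual degrees of freedom remained. Each class was set against the unweighted mean of the other 5 on the log scale. A class can therefore show a positive fold while 1 of the others has a higher level. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05 and its absolute log2 fold at least 1. Adjusted p-values are from this test throughout. Errors of log2 folds are standard errors of the fit, and levels in CPM, counts scaled to the total of each sum without TMM, are means ± SD over the 2 libraries. The fit draws the spread of each gene towards that of all genes. Its p-values and errors therefore do not show a gene's own difference between the libraries in full. Where a class had no count of a gene in either library, the fitted fold depends on the prior count, so levels and the adjusted p are given without a fold.

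Within HSC-like (hepatic stellate cell), hepatocyte-like, endothelial-like and macrophage-like nuclei, 2 subclusters were drawn by k-means (scikit-learn 1.9.0) on principal components of values centred per library, again without the listed genes. Subcluster 2, the smaller, was set against subcluster 1 in the same kind of fit on 4 sums, with 1 residual degree of freedom. With so few, the p-values and errors of this fit lean strongly on the spread pooled over genes. Genes among the clustering features or markers define the groups and are no independent result. Counts of called genes are therefore given outside the features and markers, a restriction decided after the totals had been seen, with the totals over all genes beside them. Genes outside them are not independent either. The groups were drawn from the same nuclei that were tested, so listed and other genes that vary with the features differ as well. The endothelial-like split left 5 nuclei of replicate 1 in the smaller group, under the minimum of 20, and was not tested.

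The 16 gene lists, fixed before the data were examined, were collagens, matrix and matrix remodelling, contractile genes, cytokines and growth factors secreted by HSC, HSC quiescence and retinoid genes, receptors, YAP/TAZ pathway, pericentral and periportal hepatocyte genes, hepatocyte injury and progenitor genes, lipid droplet and synthesis genes, sinusoidal and vascular endothelial genes, Kupffer cell genes, scar-associated macrophage genes, and immediate-early and stress genes. Each list is described by its counts of called members over all genes tested, with the count adjusted over the list alone beside it; where a single count is given, both were equal. The genes named were fixed by rule. These were 10 genes always named (COL1A1, COL1A2, COL3A1, HGF, CXCL12, ACTA2, LRAT, DDR1, MET and YAP1), and per list up to 3 higher and 2 lower called genes with the same direction in both libraries. Up to 5 genes per direction outside the lists, features and markers followed by the same criteria. The text prints a part of the genes the rule gives. Folds of a single library were computed with a prior count of 2. Genes on chromosome Y, XIST, TSIX, immunoglobulin, T cell receptor and HLA genes, and genes with common whole-gene deletions were left out of the clustering features and of the summed counts. They are therefore in none of the tests, counts of called genes or named genes, nor in the totals behind the scaling and CPM of the sums.

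Shares of nuclei with a UMI of a gene were taken after each nucleus was thinned at random to 2945 UMIs. Intervals are exact binomial 95% intervals, and the upper limit of a share of 0 is 3 counts over the number of nuclei; both cover counting error only. Nuclei are not replicates, so no p-value was made from them. Free RNA was profiled per library from barcodes with at most 100 UMIs. The edgeR fit was tested on simulated counts drawn from these sums. Of genes raised 4-fold, 81.6% were recovered in the HSC-like comparison, 81.3% in the hepatocyte-like one, and 96.0%, 96.0% and 76.0% in the HSC-like, hepatocyte-like and macrophage-like subclusters. Of genes raised 2-fold, 4.17%, 12.2%, 10.0%, 36.0% and 2.00% were recovered. A 2-fold change lies on the fold threshold itself, so these shares reflect that threshold as well as the spread of the data. Smaller changes mostly go uncalled because of the threshold. Genes lowered 4-fold were recovered less often, in 39.1%, 56.3%, 74.4%, 89.1% and 46.2%, and those lowered 2-fold in 2.33%, 28.3% and 11.4% in the subclusters and in none of the genes in the class comparisons, so counts of lower genes may fall short of those of higher ones for this reason alone. Unchanged genes were called in at most 0.122%. The simulated groups were fixed, with no clustering, so this rate does not cover the drawing of groups from the same nuclei. Apart from the changed genes, all simulated groups of a library had the same mean of each gene. The real classes differ in many genes, which also bears on scaling, so these rates may not hold for the class comparisons.

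The alternatives were DESeq2 1.42.0, library totals in place of TMM, no low-count filter, no library block, minima of 500 or 1000 UMIs, doublets kept, free RNA subtracted from every class but the hepatocyte-like one, the highest marker score per nucleus in place of clusters, Leiden resolution halved and doubled, Leiden clusters in place of k-means, no thinning, and each library left out. A split of the HSC-like nuclei into 3 groups, with 1000 UMIs or with doublets kept, was added after the data had been seen.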

Results

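Nuclei of 2 libraries of human cirrhotic liver next to HCC were profiled. The study asked how hepatic stellate cells (HSC), the pericytes that make scar collagen in the liver, relate to liver cancer, with attention to the HSC-derived hepatocyte growth factor gene HGF and to type I collagen and its receptor DDR1. In the non-tumour tissue the questions that can be asked are which nuclei carry these genes, and whether HSC-like nuclei fall into kinds that differ in them. The 2 replicates held 46542405 and 62522078 UMIs, of which the 3540 and 3785 nuclei kept had medians of 6651 and 7422 UMIs.

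The tissue held hepatocyte-like, cholangiocyte-like, HSC-like, macrophage-like, endothelial-like and plasma-like nuclei in both libraries, in different proportions. Hepatocyte-like nuclei made up 67.4% of replicate 1 (95% interval 65.9 to 69.0) and 28.9% of replicate 2 (27.5 to 30.4). Cholangiocyte-like nuclei, the cells lining bile ducts, made up 5.14% (4.44 to 5.92) and 21.5% (20.2 to 22.9). HSC-like nuclei made up 7.43% (6.59 to 8.34) and 15.2% (14.1 to 16.4), macrophage-like nuclei 4.58% (3.91 to 5.32) and 9.91% (8.97 to 10.9), endothelial-like nuclei 4.72% (4.04 to 5.47) and 7.21% (6.41 to 8.08), and plasma-like nuclei 1.86% (1.44 to 2.37) and 4.28% (3.66 to 4.97). T/NK-like clusters made up 7.66% (6.80 to 8.58) and B-like ones 0.480% (0.280 to 0.768) of replicate 1, and cycling nuclei 1.0% of replicate 2 (0.711 to 1.38). In replicate 2 no cluster was named T/NK-like or B-like, which follows from the naming rule and is no limit on these cells: clusters with T cell markers together with those of another class stayed unnamed and are part of its 11.9% unnamed nuclei. By the highest marker score per nucleus, 4.49% of replicate 2 were T/NK-like and 1.19% B-like. The UMI minimum, 2946 in replicate 1 and 4111 in replicate 2, bears on these shares, as T/NK-like nuclei held few UMIs (median 3386). With a minimum of 1000 UMIs the mean T/NK-like share was 23.1% in place of 3.83%, a mean over both libraries of nuclei in clusters so named.

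**Figure D1:**
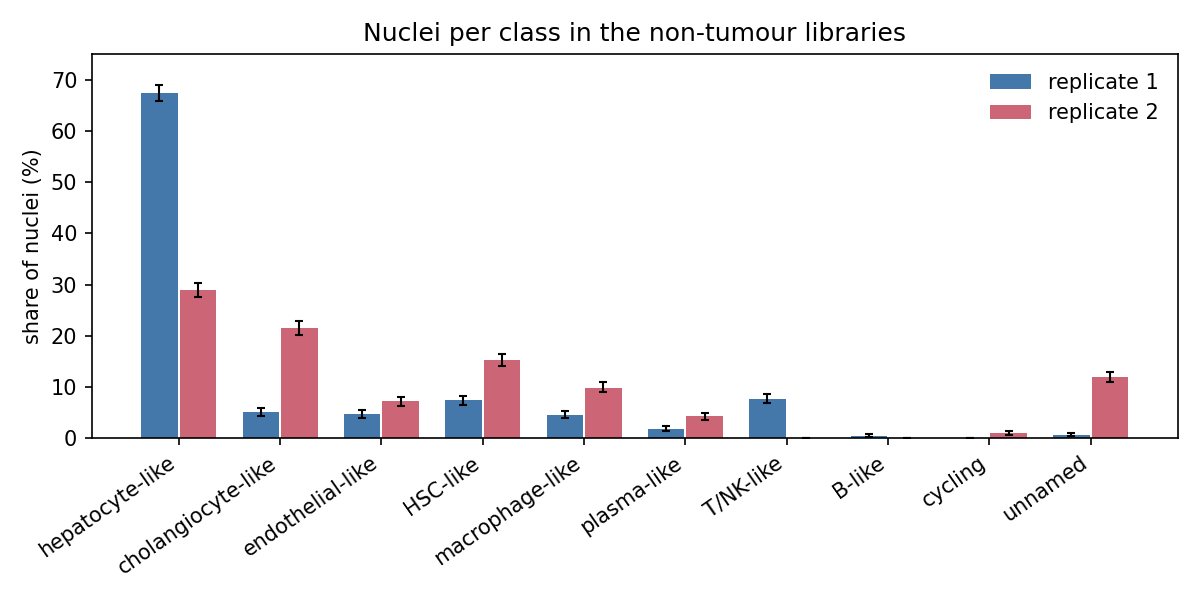
Share of nuclei per class (y axis, percent) in replicates 1 and 2 of the non-tumour tissue, with exact binomial 95% intervals as error bars. Hepatocyte-like nuclei fall from 67.4% in replicate 1 to 28.9% in replicate 2, while cholangiocyte-like nuclei stand at 5.14% and 21.5%.

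HSC-like nuclei were higher in the collagens and in most of the listed matrix genes and HSC-secreted factors. COL1A1 (ENSG00000108821, chromosome 17, 50183289 to 50201632 on GRCh38), which encodes a chain of type I collagen, reached 613 ± 509 CPM against 13.1 ± 15.8 in the other classes, a log2 fold of 6.18 ± 0.33 (n = 2 libraries, adjusted p = 1.14e-06 by edgeR). COL1A2 (chromosome 7, 94394561 to 94431232) was higher by 6.98 ± 0.41 and COL3A1 by 6.94 ± 0.45. HGF (ENSG00000019991, chromosome 7, 81699008 to 81770438), whose product is the ligand of the receptor MET, reached 793 ± 327 CPM against 18.5 ± 2.13, a log2 fold of 6.38 ± 0.41 (adjusted p = 2.93e-06). MET itself was low in HSC-like nuclei, at 5.66 ± 4.42 CPM (log2 fold -3.40 ± 0.90, adjusted p = 0.0206).

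All 17 collagens were called higher (17 adjusted over the list alone), with COL6A3 (8.24 ± 0.44) and COL14A1 (7.60 ± 0.26) among the leading ones. Of 24 matrix genes measured, 23 were higher (24 adjusted over the list alone), among them the procollagen protease gene ADAMTS2 (7.12 ± 0.29) and the thrombospondin gene THBS2 (6.95 ± 0.44). Of 9 contractile genes 8 were higher (8 adjusted over the list alone), with the smooth muscle actin gene ACTA2 at 4.34 ± 0.42 and MYL9 at 5.58 ± 0.44. The list of cytokines and growth factors had 20 of 27 genes higher and 2 lower (22 and 2 adjusted over the list alone), including the chemokine gene CXCL12 (5.10 ± 0.50; 6.74 in replicate 1 and 3.40 in replicate 2) and BMP5 (8.26 ± 0.52). NRG1 (-1.19 ± 0.30) and IGF1 (-1.09 ± 0.28) were lower, and NRG1 stood at 0.082 in the fit with a minimum of 1000 UMIs. Of 10 HSC quiescence and retinoid genes, 8 were higher and 1 lower (9 and 1 adjusted over the list alone). The neurotrophin receptor gene NGFR stood at 67.1 ± 1.23 CPM against 0.443 ± 0.603, and PPARG was lower (-3.06 ± 0.56). LRAT, the retinol esterification enzyme used as an HSC marker, was not called (adjusted p = 0.0616). Its level was 22.1 ± 24.1 CPM in HSC-like nuclei and 167 ± 17.9 in cholangiocyte-like nuclei.

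Receptors were divided, with 12 of 25 higher and 4 lower (12 and 4 adjusted over the list alone). The collagen-binding integrin gene ITGA1 (4.03 ± 0.37) and FGFR1 (4.47 ± 0.55) were higher and ERBB3 (-2.56 ± 0.55) was lower, while DDR1 was not called (7.64 ± 2.89 CPM, log2 fold 0.71 ± 0.47, adjusted p = 0.339). Of 13 YAP/TAZ pathway genes, 9 were higher (10 adjusted over the list alone), with YAP1 at 2.54 ± 0.24 and the matricellular genes CCN1 (5.33 ± 0.55) and CCN2 (5.05 ± 0.38). Among 11 immediate-early and stress genes 4 were higher (4 adjusted over the list alone), with FOS at 2.19 ± 0.31 and FOSB at 2.85 ± 0.44. In the other lists, 3 of 9 vascular endothelial genes were higher, led by the basement membrane collagen gene COL4A1 (5.41 ± 0.47), as were 4 of 13 pericentral genes, including the WNT target AXIN2 (4.69 ± 0.50), with 3 lower (5 and 4 adjusted over the list alone). Of 12 periportal genes 4 were lower and 1 higher. GPC3 (5.64 ± 0.55) was the higher member of 12 injury and progenitor genes, with 1 lower. Lipid genes had 2 higher and 2 lower of 16, sinusoidal genes 1 lower of 10 (0 adjusted over the list alone) and scar-associated genes 1 higher of 7. Of the 7 Kupffer genes 0 were called by edgeR, 0 had an unadjusted p under 0.05 and 0 were called by DESeq2; their median log2 fold was -0.98. Outside the features and markers 1243 genes were called higher and 629 lower; over all 15053 genes tested the counts were 2279 and 923.

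**Figure D2:**
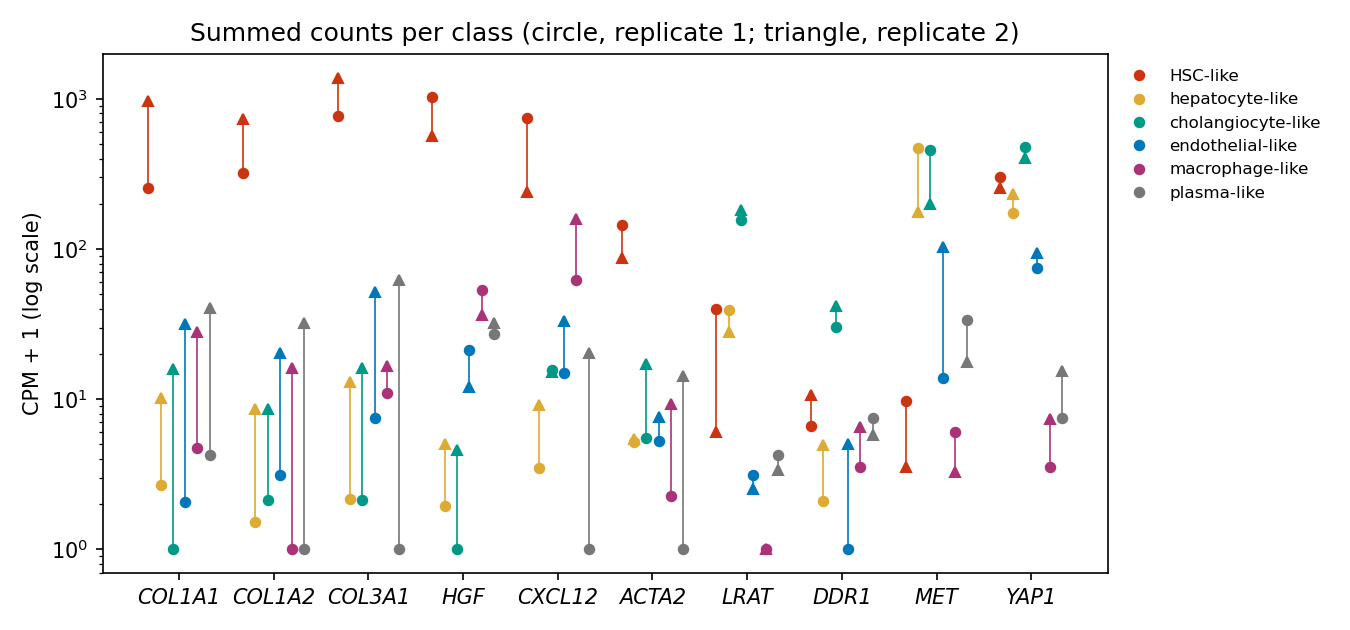
Level of the 10 genes always named (y axis, CPM + 1 on a log scale) in the summed counts of each class, with circles for replicate 1, triangles for replicate 2 and a line joining both. COL1A1, COL1A2, COL3A1, HGF and CXCL12 are highest in HSC-like nuclei, whereas LRAT and DDR1 are highest in cholangiocyte-like nuclei (167 and 35.1 CPM on average).

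Among HSC-like nuclei thinned to 2945 UMIs, HGF was found in 63.5% (57.4 to 69.3) of 263 in replicate 1 and 57.4% (53.2 to 61.5) of 575 in replicate 2, and without thinning in 68.8% and 76.3%. In hepatocyte-like nuclei it was found in 0.419% (0.201 to 0.769) and 1.19% (0.634 to 2.02), at unthinned medians of 8505 and 12316 UMIs against 4298 and 6866 in HSC-like nuclei. The highest shares outside HSC-like nuclei were those of macrophage-like nuclei, 12.3% (7.71 to 18.4) and 8.0% (5.46 to 11.2), followed by plasma-like (4.55% and 5.56%) and endothelial-like nuclei (2.99% and 2.93%). Free RNA held HGF at 37.7 CPM in replicate 1 and 96.4 in replicate 2. The shares were not corrected for it, so a part of those outside HSC-like nuclei may come from free RNA. Detection of HGF with that of COL1A1 or COL1A2 had no common direction in the libraries. In replicate 1, 99 nuclei had both, 68 HGF alone, 66 collagen alone and 30 neither, an odds ratio of 0.662. In replicate 2 the numbers were 277, 53, 197 and 48, an odds ratio of 1.27. The mean log2 odds ratio was -0.12 ± 0.67 (SD, n = 2), so that no association beyond the difference between libraries was seen. Within the subclusters described next, the odds ratio was 1.0 and 1.37 in subcluster 1 and 0.476 and 0.590 in subcluster 2 (replicates 1 and 2). The mean log2 odds ratio was 0.23 ± 0.32 in subcluster 1 and -0.92 ± 0.22 in subcluster 2 (SD, n = 2). The ratios of subcluster 2 thus had the same direction in both libraries. They rest on few nuclei and were not tested, so an association stays undecided. In replicate 1, 39 had both, 41 HGF alone, 4 collagen alone and 2 neither. In replicate 2 the numbers were 57, 10, 29 and 3.

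HSC-like nuclei split into a larger subcluster 1 and a smaller subcluster 2, which held 86 nuclei (32.7%) in replicate 1 and 99 (17.2%) in replicate 2. Whether both are HSC, or one holds other fibroblasts, was not tested. With 1000 UMIs or doublets kept, the smaller of 2 groups held too few nuclei to test (5 and 47, and 19 and 14, in replicates 1 and 2). With doublets kept and 3 groups, subcluster 2 held 28.1% and 9.25%. Subcluster 2 was higher in HGF, with 1935 ± 1168 CPM against 402 ± 80.6 (log2 fold 2.08 ± 0.42, adjusted p = 0.00997 by edgeR; 3.04 in replicate 1 and 1.13 in replicate 2). It was also higher in BMP10 (5.24 ± 0.69) and GDF2 (4.24 ± 0.47), whose products are ligands of endothelial ALK1, and in the chemokine gene CXCL14 (3.03 ± 0.56). In replicates 1 and 2 BMP10 stood at 39.8 and 36.4 CPM in subcluster 2 against 0 and 1.10 in subcluster 1. GDF2 stood at 54.0 and 81.5 against 5.56 and 2.74. The size of these folds, above all that of BMP10, thus rests on levels near the floor in subcluster 1. Type I collagen genes were not called: COL1A1 had a log2 fold of -0.36 ± 0.36 (adjusted p = 0.773) with opposite signs in the libraries (-1.19 and 0.31), and COL1A2 one of -0.16 ± 0.33. Of 25 secreted factor genes 8 were higher and 3 lower (9 and 6 adjusted over the list alone). The higher ones also included IGFBP3, IGFBP5 and RSPO3, which were named after their values were seen, and the lower ones included FGF7 (-2.82 ± 0.51) and CCL21 (-2.81 ± 0.47).

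The quiescence list had 3 of 9 genes higher (5 adjusted over the list alone), which were PPARG (4.04 ± 0.54), VIPR1 (2.41 ± 0.31) and LHX2 (1.86 ± 0.38). Matrix genes had 8 of 24 lower and 1 higher (9 and 2 adjusted over the list alone), with the proteoglycan gene VCAN at -2.18 ± 0.52, MMP19 at -2.47 ± 0.49 and ECM1 at 2.27 ± 0.35. Of 17 collagens 1 was lower, COL8A1 (-1.71 ± 0.35), the same count as over the list alone. Among the immediate-early genes, which follow stress and handling as well as signalling, 6 of 10 were lower (6 adjusted over the list alone), with FOSB at -3.39 ± 0.33 and EGR1 at -1.99 ± 0.41. The contractile list had 1 of 9 genes higher, TGFBI (2.21 ± 0.38), which encodes a matrix protein, and 1 lower, the nuclear lamin gene LMNA (-1.75 ± 0.40). Receptors had 2 of 18 lower, ITGA2 (-1.94 ± 0.41) and FGFR1 (-1.28 ± 0.28), with 1 higher when adjusted over the list alone, and YAP/TAZ genes 1 of 11 lower, CCN1 (-1.13 ± 0.31). In the other lists, 1 of 4 vascular genes was higher, SPARCL1 (3.30 ± 0.38; -2.99 with 1000 UMIs and 3 groups), as was 1 of 12 pericentral genes, each list with 1 lower gene as well when adjusted over the list alone, and 1 of 12 lipid genes, PPARGC1A (-2.18 ± 0.38), and 1 of 2 injury and progenitor genes were lower. Single libraries gave unlike sizes for VCAN (-5.48 in replicate 1 and -1.24 in replicate 2), MMP19 (-4.37 and -1.31), FGF7 (-1.42 and -4.43), CXCL14 (1.62 and 3.60), LMNA (-2.85 and -0.78) and EGR1 (-3.29 and -1.01). The standard errors printed for these folds are smaller than the gaps between the libraries, as they draw on the spread of all genes. Outside the features and markers 64 genes were higher and 120 lower, and over all 8933 tested 176 and 234. The calls rest on the library block: without it 0 genes were called by edgeR, HGF then having an adjusted p of 0.746, although 474 genes had an unadjusted p under 0.05, and DESeq2, with the block, called 21 higher and 34 lower. With free RNA subtracted the log2 fold of HGF was 2.08 ± 0.48 (adjusted p = 0.0865), and in the comparison of Leiden clusters, both lying mostly in subcluster 1, it was 0.28 (adjusted p = 0.999).

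**Figure D3:**
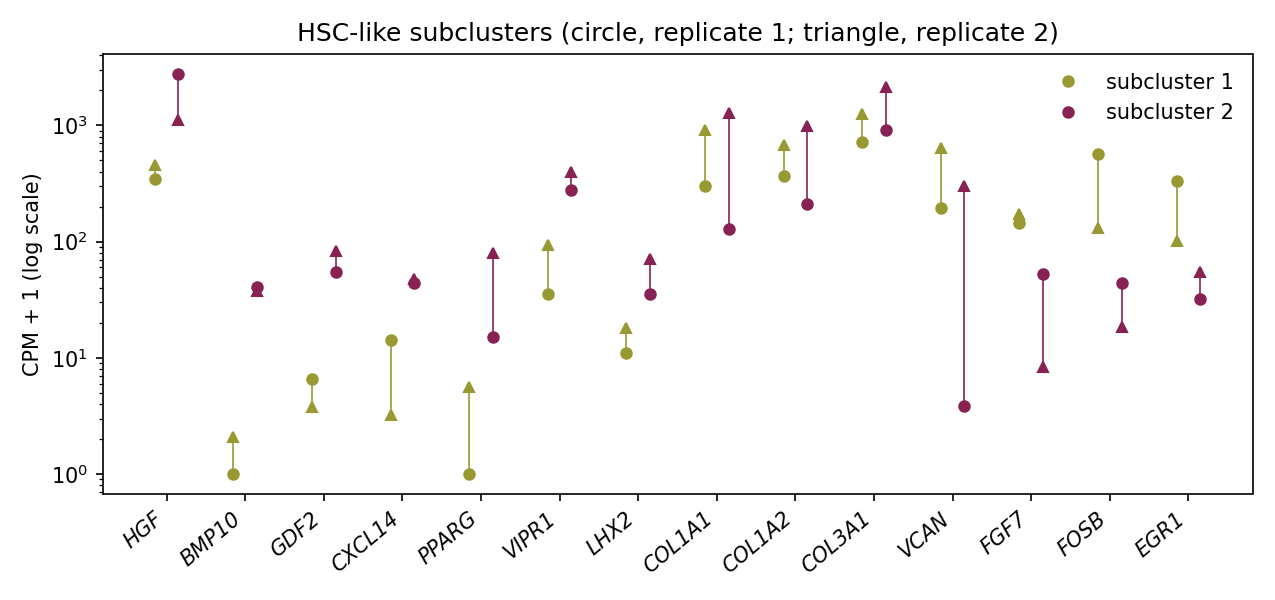
Level of 14 genes (y axis, CPM + 1 on a log scale) in HSC-like subclusters 1 and 2, with circles for replicate 1, triangles for replicate 2 and a line joining both. HGF averages 1935 CPM in subcluster 2 and 402 in subcluster 1, while the 2 libraries of COL1A1 differ in direction.

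Hepatocyte-like nuclei were higher in most of the listed zonation and lipid genes and in several receptors. MET (chromosome 7, 116672390 to 116798386), the HGF receptor, stood at 321 ± 205 CPM against 83.5 ± 27.3 in the other classes (log2 fold 4.0 ± 0.55, adjusted p = 0.000249 by edgeR), with cholangiocyte-like nuclei at a like level (326 ± 182). HGF was lower (-3.46 ± 0.63). LRAT was called higher on the log scale (adjusted p = 0.00109), although its level was 32.7 ± 8.2 CPM in hepatocyte-like nuclei and 38.7 ± 1.44 over the others, as cholangiocyte-like nuclei lead the latter. All 12 periportal genes measured were higher (12 adjusted over the list alone), including the histidine ammonia lyase gene HAL (6.65 ± 0.42) and the urea cycle gene ARG1 (6.41 ± 0.28). So were 10 of 13 pericentral genes (10 adjusted over the list alone), including CYP3A4 (6.30 ± 0.23). Of 16 lipid genes 14 were higher (14 adjusted over the list alone), such as the lipid droplet gene PLIN5 (5.49 ± 0.38).

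Of 25 receptors 12 were higher and 4 lower (12 and 6 adjusted over the list alone). The leptin receptor gene LEPR (4.34 ± 0.22) and ERBB3 (4.30 ± 0.33) were higher, and IGF1R (-5.61 ± 0.80) and FGFR1 (-5.33 ± 0.90) lower, while DDR1 was not called (-1.15 ± 0.46, adjusted p = 0.0746). Collagens had 12 of 17 lower and 2 higher (13 and 2 adjusted over the list alone), with COL1A1 at -2.02 ± 0.46 (-0.85 in replicate 1 and -2.25 in replicate 2), COL1A2 at -2.31 ± 0.55 and COL18A1 at 2.5 ± 0.34. With free RNA subtracted from the other classes, COL1A1 stood at 0.24 and COL1A2 at 1.31. Matrix genes had 16 of 24 lower (17 adjusted over the list alone) and the fibronectin gene FN1 higher (3.43 ± 0.49; 4.39 and 1.90 in replicates 1 and 2). Secreted factors had 12 of 27 lower (13 adjusted over the list alone) and 3 higher, NRG1 (4.39 ± 0.22), IGF1 (2.20 ± 0.21) and VEGFA (1.91 ± 0.37). Injury and progenitor genes had 4 of 12 higher, including AKR1B10 (4.96 ± 0.24), and 1 lower, PROM1 (-2.72 ± 0.87; 0.095 with free RNA subtracted). YAP/TAZ genes had 4 of 13 higher, with YAP1 at 2.20 ± 0.24, and 2 lower. In the remaining lists, quiescence genes had 1 of 10 higher (2 adjusted over the list alone) and 4 lower, contractile genes 2 of 9 higher and 3 lower (2 and 4 adjusted over the list alone), immediate-early genes 2 of 11 lower, sinusoidal genes 4 of 10 lower, vascular genes 7 of 9 lower and 1 higher, Kupffer genes 3 of 7 lower, and scar-associated genes 1 higher and 1 lower of 7. The genes called outside the features and markers numbered 2675 higher and 982 lower (3112 and 2188 over all genes). That split depended on scaling: with library totals it was 2035 and 1575, the median of all genes then lying at -0.28 against 0.07, and with DESeq2 2258 and 1390.

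Hepatocyte-like subcluster 2 held 327 nuclei (13.7%) in replicate 1 and 203 (18.5%) in replicate 2 (14.3% and 30.4% with a minimum of 1000 UMIs). It was higher in a broad set of genes. The apolipoprotein gene APOE stood at 2720 ± 1067 CPM against 395 ± 173 (log2 fold 2.91 ± 0.12, adjusted p = 1.89e-09 by edgeR), the lipid synthesis gene SCD was higher by 2.34 ± 0.12 and the biliary keratin gene KRT7 by 3.32 ± 0.25. Mitochondrial UMIs and hepatocyte markers were higher with it, with medians of 3.91% and 1.28% mitochondrial UMIs against 0.553% and 0.158% in subcluster 1, and hepatocyte markers at 6.07% and 10.1% of UMIs against 1.69% and 2.74%. Of the lists, 6 of 13 injury and progenitor genes, 7 of 11 immediate-early genes such as JUNB (1.98 ± 0.15), 5 of 17 lipid genes, 6 of 13 collagens, 6 of 18 matrix genes (7 adjusted over the list alone), 5 of 13 secreted factors, 4 of 5 sinusoidal genes, 3 of 12 periportal genes, 2 of 25 receptors (1 adjusted over the list alone), 2 of 11 YAP/TAZ genes, 2 of 5 quiescence genes, 1 of 15 pericentral genes, 1 of 7 contractile genes, 1 of 6 vascular genes, 1 of 2 Kupffer genes and 1 of 5 scar-associated genes were higher. The collagens differed between libraries, with list medians of -0.0051 in replicate 1 and 1.34 in replicate 2: COL1A1 had log2 folds of -0.49 and 2.43 in replicates 1 and 2, and COL3A1 of -0.36 and 2.39. Over genes outside the features and markers, 1661 were higher and 93 lower (1785 and 140 of 15101 tested). Without the library block edgeR called 0 genes, with 1541 at an unadjusted p under 0.05; DESeq2, with the block, called 1177 higher and 10 lower.

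Cholangiocyte-like nuclei carried DDR1 (chromosome 6, 30876421 to 30900156), the receptor of fibrillar collagen, at 35.1 ± 8.24 CPM against 4.37 ± 1.73 in the other classes (log2 fold 3.12 ± 0.40, adjusted p = 0.000322 by edgeR). They were also higher in MET (3.53 ± 0.55) and YAP1 (3.07 ± 0.23), and LRAT was highest there, at 167 ± 17.9 CPM against 11.9 ± 6.67 (adjusted p = 4.27e-05). The hepatocyte injury and progenitor list had 10 of 12 genes higher (11 adjusted over the list alone), among them PROM1 (7.82 ± 0.43) and the osteopontin gene SPP1 (5.34 ± 0.58). That list was drawn up for hepatocytes and holds the biliary keratin gene KRT7, also called here. Its calls in this class therefore do not tell injury from the identity of the class. Receptors had 12 of 25 higher and 4 lower (13 and 4 adjusted over the list alone), with FGFR2 at 5.26 ± 0.39, and YAP/TAZ genes 7 of 13 higher and 1 lower. The secreted factor list had 6 of 27 higher and 5 lower (6 and 6 adjusted over the list alone), with TGFB2 at 5.50 ± 0.38. Collagens had 4 of 17 higher and 6 lower (4 and 8 adjusted over the list alone), with COL1A1 at -2.13 ± 0.52, and matrix genes 2 of 24 higher and 8 lower (4 and 12 adjusted over the list alone). The called genes outside the features and markers were 1661 higher and 474 lower (2442 and 1029 over all genes), against 813 and 112 with the highest marker score per nucleus.

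Endothelial-like nuclei had all 10 sinusoidal genes and all 9 vascular genes higher (10 and 9 adjusted over the list alone), with the scavenger receptor gene STAB2 at 10.27 ± 0.53 and the von Willebrand factor gene VWF at 7.49 ± 0.39 (adjusted p = 1.41e-06 and 1.37e-06 by edgeR). The libraries drew this class from unlike clusters: in replicate 1 its 167 nuclei formed 1 cluster led by STAB2, whereas in replicate 2 the cluster with VWF and PLVAP among its leading genes held 182 of 273 nuclei and that with STAB2 held 59. Collagens had 6 of 17 higher and 1 lower (7 and 1 adjusted over the list alone), and receptors 10 of 25 higher and 2 lower (11 and 3 adjusted over the list alone), including IGF1R (3.78 ± 0.44). YAP/TAZ genes had 4 of 13 higher, including the TAZ gene WWTR1 (4.25 ± 0.35), and 2 lower. COL1A1 stood at -0.77 ± 0.47 (adjusted p = 0.296). A total of 957 genes outside the features and markers were higher and 598 lower (1888 and 771 over all genes); the lower count was 267 with free RNA subtracted and 335 with doublets kept.

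Macrophage-like nuclei had all 7 Kupffer genes higher (7 adjusted over the list alone), including the scavenger receptor gene MARCO (7.43 ± 0.35), and 4 of 7 scar-associated genes (5 adjusted over the list alone), including GPNMB (7.32 ± 0.34, adjusted p = 1.3e-06 by edgeR). CXCL12 was higher by 1.97 ± 0.52. YAP/TAZ genes had 9 of 13 lower, with YAP1 at -4.68 ± 0.41, and AXL higher (5.46 ± 0.37). Receptors had 10 of 25 lower and 2 higher (11 and 2 adjusted over the list alone), and collagens 8 of 17 lower. In all, outside the features and markers, 1239 genes were higher and 1158 lower (2130 and 1666 over all genes); with the highest marker score per nucleus these were 577 and 55.

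Macrophage-like subcluster 2, with 83 and 175 nuclei (51.2% and 46.7% of the class), was lower in 5 of 7 Kupffer genes (6 adjusted over the list alone) and 3 of 6 scar-associated genes (4 adjusted over the list alone). The Kupffer cell gene CD5L had a log2 fold of -6.75 ± 0.50 (1.57 ± 2.21 CPM against 201 ± 148, adjusted p = 0.00804 by edgeR), TIMD4 stood at -6.22 ± 0.57, GPNMB at -4.65 ± 0.33 and CXCL12 at -3.84 ± 0.36. VCAN, a gene of monocytes, was higher (3.41 ± 0.30), as were CD1E (6.37 ± 0.68), a gene of dendritic cells, and ANGPT1 (5.00 ± 0.91). With the Leiden resolution doubled, 112 nuclei of replicate 2 were named dendritic-like and 263 macrophage-like, in place of 375 macrophage-like ones. Of 10 immediate-early genes 0 were called by edgeR, 1 had an unadjusted p under 0.05 and 0 were called by DESeq2. Outside the features and markers 59 genes were higher and 134 lower (162 and 259 of 8262 tested). Without the library block edgeR called 0, with 1130 at an unadjusted p under 0.05; DESeq2, with the block, called 29 higher and 88 lower.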

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

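Barcodes between 1000 UMIs and the UMI threshold of each library lie outside the comparisons of the report. They are given here because their T/NK-like share was above the limit that a count of 0 allows, a low bar that a few barcodes would pass; the share at or above the threshold says more. In a clustering of all barcodes of at least 1000 UMIs, T/NK-like barcodes made up 41.2% of these (844 of 2051, exact binomial 95% interval 39.0 to 43.3) in replicate 1 and 45.2% (2289 of 5060, 43.9 to 46.6) in replicate 2. At or above the threshold they made up 7.48% and 1.08% in the same clustering. Their median UMI counts below the threshold were 2084 and 2157, against 1837 and 1797 in hepatocyte-like barcodes below it.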

How the results depend on the processing

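The splits of HSC-like nuclei into 3 groups were added after the data had been seen. With 2 libraries, leaving out 1 gives folds with no test and no count. The genes named kept their direction and side of the threshold in 421 of 447 values for HSC-like nuclei, 360 of 390 for hepatocyte-like, 245 of 259 for endothelial-like, 217 of 239 for macrophage-like and 248 of 260 for cholangiocyte-like ones. For the subclusters these were 165 of 248 (HSC-like), 134 of 181 (hepatocyte-like) and 85 of 109 (macrophage-like). Calls were lost by 21 (HSC-like), 23 (hepatocyte-like), 13 (macrophage-like) and 9 (cholangiocyte-like) of these values, and by 69, 40 and 22 in the subclusters in the same order as above. Calls were gained by 3, 4, 6 and 1 in the same classes, by 4 in endothelial-like nuclei and by 2 in HSC-like subclusters. The highest marker score accounted for 6, 12, 6 and 4 of the lost calls in the classes. Uncalled values changed sign in 10 cases in endothelial-like nuclei, with 5 of these under the highest marker score and 4 with free RNA subtracted. Called values that turned, and changed counts of called genes, are given below; where no reason stands beside a value, the cause was not tested.

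Without the low-count filter more genes were tested, and those called higher numbered 1893 in HSC-like and 4141 in hepatocyte-like nuclei, 106 higher and 247 lower in HSC-like subclusters, and 276 and 428 in macrophage-like subclusters. With the highest marker score per nucleus the counts fell to 1534 and 393 in hepatocyte-like, 577 and 55 in macrophage-like and 813 and 112 in cholangiocyte-like nuclei. Library totals gave 1575 lower in hepatocyte-like nuclei and 94 higher in macrophage-like subclusters.

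Without the replicate block edgeR called 0 higher and 0 lower in the HSC-like, hepatocyte-like and macrophage-like subclusters, with 474, 1541 and 1130 genes at an unadjusted p under 0.05. DESeq2, with the block, called 21 and 34, 1177 and 10, and 29 and 88. HGF in HSC-like subclusters had an adjusted p from 7.11e-08 without the low-count filter to 0.999 between Leiden clusters.

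Subtracting free RNA gave 23 higher and 33 lower in HSC-like subclusters, 20 and 62 in macrophage-like subclusters, and 267 lower in endothelial-like nuclei (335 with doublets kept). In hepatocyte-like nuclei it moved COL1A1 to 0.24, COL1A2 to 1.31 and PROM1 to 0.095, by construction in part, since only the other classes are lowered.

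Leiden clusters in place of k-means gave 3 higher and 2 lower in HSC-like nuclei and turned LMNA (0.66), CCL21 (0.67), CCN1 (0.21), FOSB (1.14) and EGR1 (0.58). In hepatocyte-like nuclei they gave 7 and 1 and turned COL3A1 (-1.54), CYP1A2 (-2.05), DGAT2 (-0.16) and SCD (-0.80). These clusters compare other nuclei: of the group standing for subcluster 2, only 3.70% and 8.85% (HSC-like) and 1.68% and 4.76% (hepatocyte-like) lay in it in replicates 1 and 2. With 1 library left out, COL1A1 in hepatocyte-like subclusters ranged from -0.49 (without replicate 2) to 2.43 and COL3A1 from -0.36 to 2.39.

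With at least 1000 UMIs, NRG1 in HSC-like nuclei stood at 0.082, macrophage-like subclusters had 194 higher and 293 lower, and hepatocyte-like subclusters 402 lower. With 3 groups, HSC-like subclusters had 20 and 17, SPARCL1 stood at -2.99, and HGF, at 2.10, lost its call, which it held with doublets kept and 3 groups. The mean T/NK-like share was 23.1% with 1000 and 22.2% with 500 UMIs, against 3.83%. The mean B-like share was 1.61%, 1.65% and, by marker score, 1.82%, against 0.240%.

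No value was had for endothelial-like subclusters, for 2 HSC-like groups with 1000 UMIs or doublets kept, for macrophage-like subclusters with doublets kept or Leiden clusters, and for hepatocyte-like subclusters with free RNA subtracted.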

Other observations

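Clusters within a class differed in further genes, given here as 1 value per cluster without a test. Among hepatocyte-like nuclei of replicate 1, cluster 1 held 5428 CPM of the pericentral gene CYP3A4 and 476 of the periportal gene HAL, while cluster 3 held 735 and 2679. KRT23 and AKR1B10, genes of injured hepatocytes, stood at 50.3 and 140 CPM in cluster 2 of replicate 1, at 7.71 and 100 in cluster 8 and at 0.531 and 0.265 in cluster 3 of that library. In replicate 2 all hepatocyte-like clusters carried both, from 19.4 to 62.6 CPM of KRT23 and from 13.04 to 154 of AKR1B10.

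Among HSC-like clusters of replicate 2, cluster 4 had 1313 CPM of the elastin gene ELN, 1560 of CCN2 and 386 of HGF, and cluster 5 had 883, 835 and 732. Cluster 23, of 17 nuclei, is left out here, as a cluster with like leading genes was named smooth muscle-like with a minimum of 1000 UMIs. In replicate 1, cluster 13 had 3149 CPM of HGF and 131 of COL1A1, and cluster 9 had 361 and 291. Macrophage-like cluster 17 of replicate 2 had 945 CPM of MARCO and 6.51 of VCAN, and cluster 10 had 14.4 and 163. Among endothelial-like clusters of that library, cluster 9 had 2321 CPM of VWF and 252 of STAB2, and cluster 18 had 210 and 2339. Cluster 21 had 528 and 1310, with 282 of CCL21.

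The tests named here as chosen later were chosen only after the result was seen. The first pattern was the higher level of 8 secreted factor genes in HSC-like subcluster 2. An immediate-early response as its cause stays open. Among nuclei with no immediate-early UMI the median log2 ratio was 2.26 of that over all nuclei in replicate 1 and 0.470 in replicate 2, but only 2 and 14 nuclei of subcluster 1 remained. Among nuclei under their library's median immediate-early share (chosen later) it was at least 0.965, but the subclusters still differed in that share, with medians of 0.0826% and 0.0434% in replicate 1 and 0.0827% and 0.0373% in replicate 2. Among nuclei paired by that share (chosen later; 61 and 99 pairs) the ratio was 0.724 in replicate 1 (bootstrap 95% interval 0.502 to 1.14), short of the bound of 0.75 set for it, and 1.05 in replicate 2 (0.772 to 1.29). For genes other than IGFBP5 (chosen later) no class exceeded 0.0981 of the level in subcluster 2, against RNA from another class, while IGFBP5 reached 1.11 of it in endothelial-like nuclei of replicate 2 and stays open, although these held 1.07 CPM in replicate 1. Free RNA as the whole cause is argued against by its own level of these genes (chosen later), at most 0.301 of that in subcluster 2. Subtracting it decides nothing, as both subclusters held nearly the same share of it: the median log2 fold was 2.41 (2.38 before; median standard error 0.44 and 0.40), with 6 of 8 genes still called, and HGF lost its call at the same fold of 2.08, its standard error growing from 0.42 to 0.48. No biological explanation was tested, as the design holds no second group.

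The second pattern was the broad rise in hepatocyte-like subcluster 2. Of the genes called higher, at least 94.0% were higher in free RNA than in subcluster 1, against 29.3% and 50.7% of genes not called (replicates 1 and 2), as free RNA needs, though hepatocyte cytoplasm kept with the nucleus could give the same. As the whole cause (chosen later) it would need at least 23.4 times the free RNA per nucleus found in any other class, and 436% of the UMIs in replicate 2, which argues against it. Cytoplasm alone (chosen later) would leave markers of other classes unmoved; their median log2 fold was 1.02, with quartiles of -0.28 and 1.57 and library medians of -0.06 and 0.85, so it stays open. No biological explanation was tested.

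The third pattern was cluster 12 of replicate 2, with 131 nuclei (3.46%) carrying hepatocyte and cholangiocyte markers. Doublets are argued against by a median UMI count of 0.410 of the sum of both classes' medians. In addition, 4 genes lay above 2 times the highest cluster of either class, against at most 1 in 100 simulated sets. Of these, JCHAIN and PLXNC1 were named after their values were seen. The count of genes is weaker ground. JCHAIN (83.3 against 14.5 CPM) is one of the plasma markers, so RNA of plasma nuclei could raise it, and the genes not named stood at only 22.2 and 13.5 CPM. For free RNA added to nuclei of one class, the comparison written beforehand (hepatocyte markers at 0.420 of free RNA) went with it, but that value did not say which class the RNA was added to. In tests of each class, chosen later, cholangiocyte markers stood at 1.31 times free RNA, against free RNA on hepatocyte nuclei, and free RNA on cholangiocyte nuclei (34.0%) would leave 3.20 times the cholangiocyte markers seen, or 2.63 times from the cholangiocyte-like cluster that comes closest; a kind of cholangiocyte with fewer of these markers was not tested. Nuclei of both classes clustered together stay open. With the Leiden resolution halved 77.1% of the cluster were named cholangiocyte-like and 22.9% hepatocyte-like, and with a minimum of 1000 UMIs 72.5% and 27.5%. Moreover 86.3% had at least 3 UMIs of both marker sets, but so had 99.6% of cholangiocyte-like and 61.6% of hepatocyte-like nuclei. No biological explanation was tested.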
